A study of Homo sapiens with 8 samples.

How the data were processed

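The series compared T3M4 pancreatic cancer cells carrying a control guide RNA with cells carrying a guide RNA against METTL13, by RNA-seq and by ribosome profiling of the same kind of lysate. Per the labels' protocols, RNA-seq used stranded poly(A) libraries with paired-end reads of 150 bp, and ribosome profiling pulled down nuclease-treated ribosomes on beads that carry a puromycin analog. The deposited table holds raw counts per gene symbol for 8 libraries, 2 in each of 4 groups, made by the authors before deposit. Per the submitters' processing notes, the tools were HISAT2 2.0.4, featureCounts, cutadapt 1.18, UMI-tools and Bowtie 1.2.2 with the hg38 build, and the notes give neither their order nor which served which assay. It is not stated whether reads that align to several places were counted, whether footprint counts are of unique molecules, or which annotation and strand setting were used. Genes with near-identical copies or pseudogenes are therefore uncertain, above all in the short footprints.

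The table has 14668 gene symbols, all of which matched protein-coding genes of the RefSeq table for GRCh38.p14, the source of the coordinates given. It holds none of the mitochondrially encoded genes, 66 genes had 0 counts in all libraries, and 354 had no footprint. Library totals ran from 20860953 to 48353722 counts in RNA-seq and from 6063885 to 9837253 in footprints. A count of 0, which allows up to 3 counts, corresponds to at most 0.144 CPM in the shallowest RNA library and 0.495 CPM in the shallowest footprint library, for counting error only.

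Groups followed the labels. Counts were fitted with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test, with TMM factors and the default expression filter within each assay, on the 4 RNA libraries and on the 4 footprint libraries apart. Translational efficiency was the interaction term of one model over all 8 libraries, on genes that passed the filter in both assays. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and an adjusted p below 0.05 counted as passed. Values per library are TMM-normalised CPM, and standard errors are the fold change over the square root of F. The common biological coefficient of variation was 0.337 in RNA, 0.0992 in footprints and 0.261 in the joint model.

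Gene lists were fixed before the data were examined. They covered eEF1A methyltransferases, elongation factors, cytosolic ribosomal proteins, initiation factors, aminoacyl-tRNA synthetases, ATF4 targets, the endoplasmic reticulum unfolded protein response, immediate early genes, ERK output genes, YAP/TEAD targets, G1/S and DNA replication, G2/M and mitosis, p53 targets, cholesterol biosynthesis, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded proteins, mitochondrial ribosomal proteins, proteasome subunits, heat shock and chaperonin, NRF2 targets, interferon-stimulated genes, NF-kB and inflammatory cytokines, extracellular matrix, mesenchymal and epithelial markers, basal-like and classical pancreatic cancer subtypes, replication-dependent histones, and markers of fibroblasts, leukocytes and an embryonic kidney line. Lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over the lists of each contrast. fry's directional test asks whether the genes of a list move one way on balance and does not compare them with other genes.

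Genes were named by a rule set before the data were examined: METTL13, EEF1A1, EEF1A2 and MYC among those always named; per contrast the 10 largest rises and 10 largest falls in log2 fold change among genes past the threshold with a mean of at least 5 CPM and no overlap of the arms, or the 5 smallest p where none passed; and up to 4 members of each list described, by smallest adjusted p. A few genes that the rule took are not reported. Names outside the rule are marked where they occur. The rule also named GAGE copies with nearly equal counts.

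Each fit was tested on simulated counts drawn for the real genes with 200 changed genes. Each gene was drawn independently, so deviations shared across genes of a library were left out. In them a 2-fold change was recovered for 6% of genes in RNA, 79% in footprints and 0% for efficiency, and a 4-fold change for 70%, 94% and 30%. A shift put into the ribosomal protein list of the simulated counts passed camera at the preset correlation in all 3 contrasts, where 1 list besides it also passed in footprints and 1 for efficiency, but not with an estimated correlation (adjusted p = 0.306 in RNA, 0.0971 in footprints and 0.0668 for efficiency). A list that misses with an estimated correlation is therefore not shown to be unchanged. Since genes were drawn independently, the simulated counts do not test the preset correlation for lists whose genes vary together.

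Alternatives set before the data were examined were DESeq2 1.42.0 and limma voom, other size factors, no filter and a filter of 50 counts, a replicate or lysate block, the fit of all 8 libraries for single assays, a minimum log2 fold change of 1, and each library left out in turn. Left-out fits with 1 library in an arm assume that it varies like the others. A planned test of codon content against efficiency was not run, since no coding sequences were available. No groups of 3 or more existed, so other splits of the samples were not counted.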

Results

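T3M4 is an established human pancreatic cancer cell line. Cells expressing a guide RNA against METTL13 (sgMETTL13) were compared with cells expressing a control guide (sgControl). METTL13 is the methyltransferase that modifies the N terminus and a lysine of the translation elongation factor eEF1A. The cells were kept without serum for 18 h and then given 10% FBS for 2 h before lysis. RNA-seq of poly(A) RNA measured mRNA abundance, and ribosome profiling measured the fragments of mRNA protected by ribosomes (footprints). Each of the 4 groups held 2 libraries, 8 in all. RNA libraries totalled 36436106 and 20860953 counts in sgControl replicates 1 and 2, and 48353722 and 39899139 counts in sgMETTL13 replicates 1 and 2. Footprint libraries were shallower, at 8181707 and 6063885 counts in sgControl and 9837253 and 8916807 counts in sgMETTL13. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries.

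METTL13, on chromosome 1 at 171781660 to 171797716 (GRCh38), was the targeted gene and was lower in every sgMETTL13 library. Its footprints fell from 65.2 and 57.8 CPM (counts scaled to library size) in sgControl to 20.1 and 26.2 CPM in sgMETTL13, a log2 fold change of -1.41 (SE 0.164, n = 2 per arm). The footprint change passed edgeR's quasi-likelihood test over all genes (adjusted p = 6.38e-07). METTL13 mRNA read 89.7 and 71.4 CPM in sgControl and 25.2 and 35.1 CPM in sgMETTL13, a log2 fold change of -1.42 with SE 0.406. That mRNA difference did not pass over all genes (edgeR adjusted p = 1, unadjusted p = 0.0046). Without sgMETTL13 RNA replicate 2 it was -1.68 and passed, and fitting all 8 libraries in one model left the footprint change at -1.41 but ended its call. Footprints per mRNA of METTL13 differed by 0.02 on the log2 scale with SE 0.403.

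**Figure D1:**
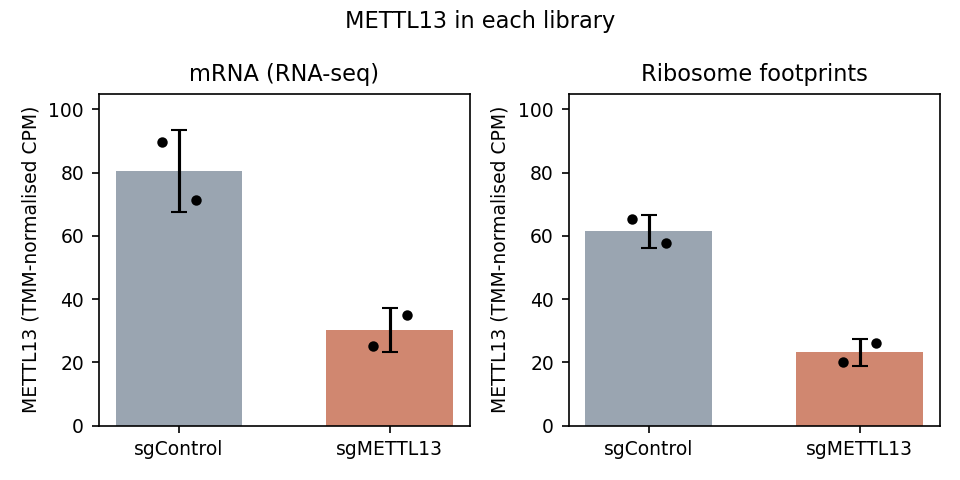
METTL13 abundance (TMM-normalised CPM) in RNA-seq (left) and ribosome footprints (right); bars are means, error bars 1 SD and points the 2 libraries of each arm. Both sgMETTL13 libraries, at 25.2 and 35.1 CPM in mRNA and 20.1 and 26.2 CPM in footprints, lay below both sgControl libraries.

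The substrate of METTL13 is encoded by EEF1A1 and EEF1A2, the paralogs of the factor that delivers aminoacyl-tRNA to the ribosome. EEF1A1 footprints rose from 23.71 and 20.01 CPM to 41.45 and 40.51 CPM, a log2 fold change of 0.90 (SE 0.166, edgeR adjusted p = 0.000354), while its mRNA read 10800 and 9232 CPM in sgControl and 9049 and 9157 CPM in sgMETTL13. EEF1A2 footprints fell by 0.55 on the log2 scale (SE 0.156, edgeR adjusted p = 0.0117). Among 13 measured elongation factors 3 rose in footprints and 1 fell (4 and 2 adjusted over the list alone), the others that rose being EEF1E1 at 0.74 and EIF5A2 at 0.73. The list as a group did not pass camera, a gene set test (adjusted p = 0.331). Among 5 eEF1A methyltransferases METTL13 alone passed in footprints, also when adjusted over the list alone, and EEF1AKMT1 read 0.43 (SE 0.210), EEF1AKMT2 0.43 (SE 0.242) and EEF1AKMT3 0.13 (SE 0.319). The median of these 5 genes was 0.13 while their mean was -0.08, and camera gave an adjusted p of 0.749. EEF1A1 footprints were far below its mRNA level, and it has pseudogene copies that can share short reads. EEF1A2 lost its call without sgControl replicate 2 (log2 fold change -0.44) or sgMETTL13 replicate 2 (-0.47), and EEF1E1 and EIF5A2 lost theirs without at least 1 library.

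Footprint abundance differed between the arms for many genes. The largest gains were in GAGE12G, a cancer-testis antigen gene on chromosome X, which rose from 32.7 and 25.7 CPM to 138.3 and 150.5 CPM (log2 fold change 2.30, SE 0.153), and in the ribosomal protein gene RPL31, which rose from 5.20 and 5.47 CPM to 24.1 and 23.7 CPM (2.16, SE 0.219). The histone gene H2BC21 rose by 1.85 and GAGE2A by 1.69. GAGE13, GAGE12C, GAGE12F, GAGE12E, GAGE12B and GAGE12J rose by 1.66 to 1.67. Their footprint counts were nearly equal in every library, so these 6 genes amount to 1 measurement of shared reads. GAGE2A counts (871 and 425 in sgControl, 2480 and 2973 in sgMETTL13) lay close to those of GAGE13 (951 and 463, 2676 and 3166). GAGE2A is therefore not clearly a separate gain. All 12 GAGE genes tested passed, but with shared reads they are not 12 separate results. The largest losses included the homeobox genes NKX1-2 and IRX3, with log2 fold changes of -2.64 and -1.69, the forkhead gene FOXD1 at -2.23, and SOX12 at -1.61. HMGA2, an architectural chromatin protein of tumours and embryonic tissue, fell from 95.8 and 149.1 CPM to 31.3 and 29.5 CPM (log2 fold change -2.00, SE 0.170). UBE2M, the conjugating enzyme of the ubiquitin-like modifier NEDD8, had a log2 fold change of -1.92 (SE 0.181), IER5L -2.23, INKA1 -2.03, NAP1L5 -1.76 and BORCS6 -1.62. Each of these genes kept its call with any 1 footprint library left out. For every loss named here sgControl replicate 2 lay above sgControl replicate 1, as in FOXD1 at 142.8 against 81.2 CPM. The 2 control libraries therefore already differed along the direction of these losses.

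Across 10714 genes tested, 2245 differed in footprints (edgeR adjusted p below 0.05), 958 higher and 1287 lower in sgMETTL13, and 333 of them changed by a log2 of 1 or more. The arms did not overlap in 64.1% of the tested genes in footprints and in 11.95% in mRNA, where chance gives 33.3% for 2 against 2, but genes of a library can deviate together, so neither share is a test of the arms. The count depended on the libraries and the model: 824 genes passed without sgControl replicate 2, 701 without sgMETTL13 replicate 2 and 1479 with DESeq2, and none passed in the fit of all 8 libraries, where the common coefficient of variation was 0.261 against 0.0992 in the footprint libraries alone. Of the 109 genes taken by the naming rule that passed in footprints, many lost their calls with at least 1 footprint library left out. None of the 109 changed sign, but that was nearly fixed beforehand. The arms did not overlap in 2243 of the 2245 calls, which leaves hardly any room for 1 left-out library to turn a sign.

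Many ribosomal protein genes had more footprints in sgMETTL13, while initiation factors and synthetases had members that passed in both directions. Of 72 cytosolic ribosomal proteins, 37 rose and none fell (44 and 2 adjusted over the list alone), with a median log2 fold change of 0.46. RPS3 rose by 0.98, RPL5 by 0.81 and RPS4X by 0.78. The list passed camera with a preset correlation (adjusted p = 1.88e-13) but not with an estimated correlation (adjusted p = 0.474). In simulated counts, with genes drawn independently, the estimated correlation also missed a shift put into this list, so the miss does not decide. The pass at the preset correlation does not decide either, since the correlation estimated within the list was 0.254, against the preset 0.01. In the simulated footprints 1 list besides this one also passed at the preset correlation. Of 35 initiation factors 9 rose and 3 fell (the same counts adjusted over the list alone), with EIF3F at 1.2, EIF2S2 at 0.88, EIF3E at 0.70 and EIF3L at 0.63. Camera gave that list an adjusted p of 0.0374, and an adjusted p of 0.474 with an estimated correlation. Among 20 cytosolic aminoacyl-tRNA synthetases 5 rose and 2 fell (8 and 2 adjusted over the list alone), including GARS1 at 0.60, RARS1 at 0.63 and FARSB at 0.57 upward. FARSA, the partner subunit of FARSB in phenylalanyl-tRNA synthetase, had a log2 fold change of -0.57. The synthetase list did not pass (camera adjusted p = 0.069). Every ribosomal protein tested has numbered pseudogenes in the RefSeq annotation, so short footprints of these genes can match more than 1 place. Without sgMETTL13 replicate 2 the ribosomal proteins that rose numbered 14 and the initiation factors 3, without sgControl replicate 2 the initiation factors numbered 5, and without sgControl replicate 1, 5 ribosomal proteins fell. The initiation factor list missed the threshold without sgControl replicate 1 (camera adjusted p = 0.0503) or sgMETTL13 replicate 1 (0.0535), and the synthetases passed without sgControl replicate 2 (0.026) or sgMETTL13 replicate 2 (0.0392). EIF3L, RARS1, FARSA and FARSB lost their calls without at least 1 library.

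**Figure D2:**
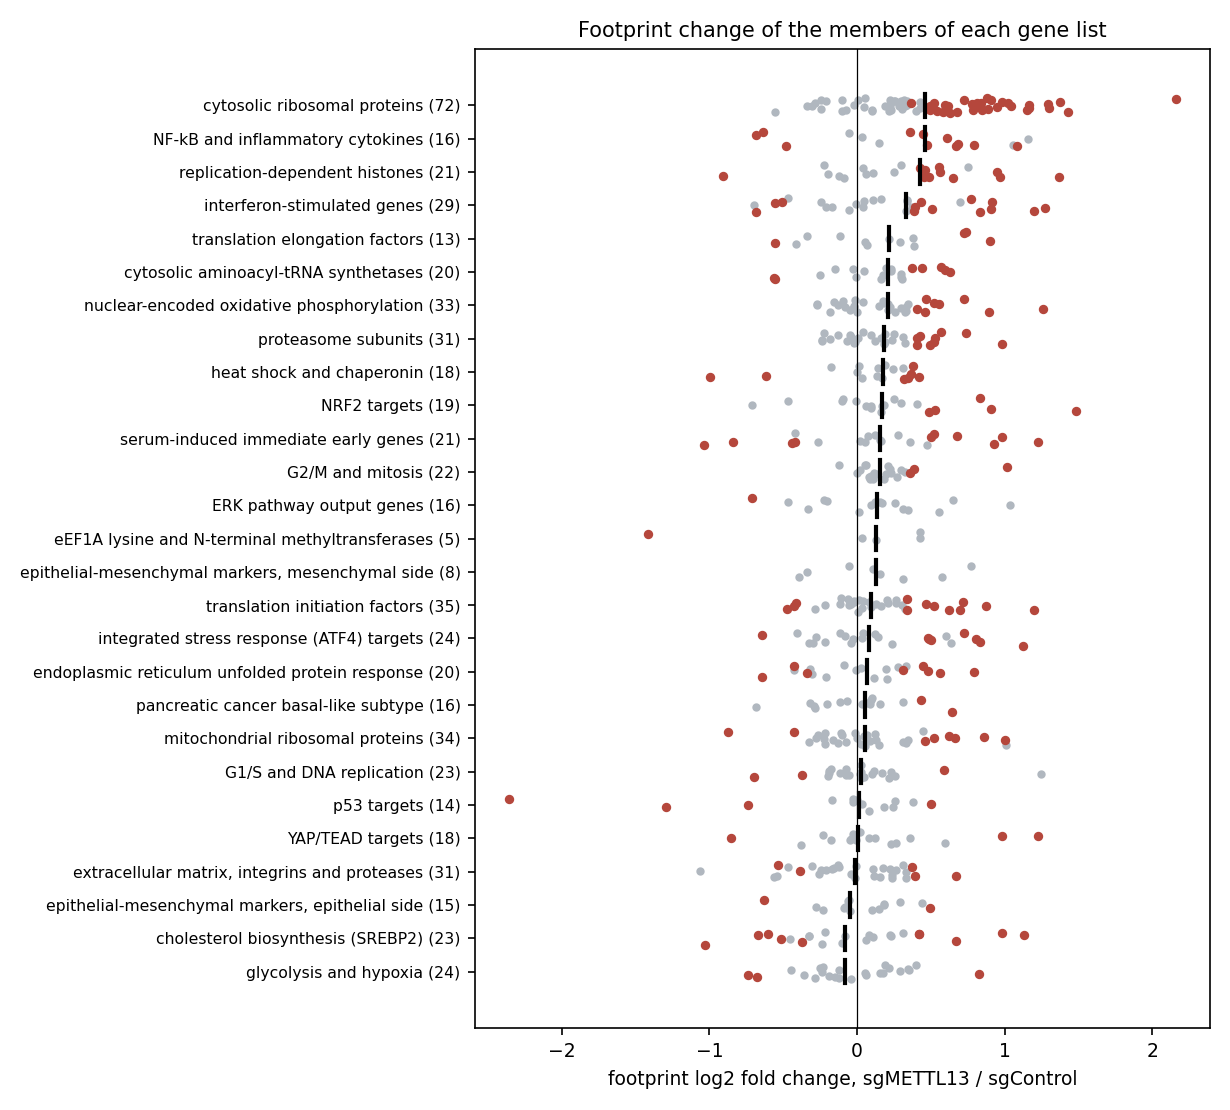
Footprint log2 fold change (sgMETTL13 over sgControl, horizontal axis) of the measured members of each gene list, with the number measured in parentheses; red points passed edgeR at an adjusted p below 0.05, grey points did not, and black bars are medians. Ribosomal proteins and NF-kB targets had the highest medians, 0.46 each, and 37 of 72 ribosomal proteins passed the threshold, all of these above 0.

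Among replication-dependent histone genes, whose mRNAs end in a stem-loop and lack a poly(A) tail, more members rose in footprints than fell. Of 21 measured, 10 rose and 1 fell (12 and 1 adjusted over the list alone), with H2BC4 at 1.37, H2BC9 at 0.97 and H2BC11 at 0.95 against H3C1 at -0.90. The histone list passed camera (adjusted p = 0.000773, but 0.474 with an estimated correlation). Whether histone genes share short footprints with each other was not measured. Among nuclear-encoded subunits of oxidative phosphorylation 8 of 33 rose and none fell, also when adjusted over the list alone, led by UQCRB at 1.26, NDUFB5 at 0.90, ATP5F1C at 0.72 and ATP5F1B at 0.47. Proteasome subunits gave 9 of 31 that rose and none that fell, again the same when adjusted over the list alone, with PSMC6 at 0.99, PSMA1 at 0.74, PSMA4 at 0.53 and PSMC2 at 0.52. Both lists passed camera (adjusted p = 0.00897 and 0.0173), and for both the adjusted p with an estimated correlation was 0.474. Without sgMETTL13 replicate 2 the members that rose numbered 3 histones, 2 oxidative phosphorylation subunits and 2 proteasome subunits, and ATP5F1C, PSMA4 and PSMC2 lost their calls; without sgControl replicate 2 the oxidative phosphorylation and proteasome members that rose numbered 3 each. Without sgControl replicate 1 the oxidative phosphorylation members that rose numbered 14 and 1 member fell, as did 1 proteasome subunit, without sgMETTL13 replicate 1 the proteasome members numbered 5, and ATP5F1B and PSMA1 lost their calls without at least 1 library.

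Some inflammatory and antioxidant genes also rose in footprints. Of 16 NF-kB targets and inflammatory cytokines 8 rose and 3 fell (10 and 3 adjusted over the list alone), with a median log2 fold change of 0.46. The cytokine genes IL1A and CXCL8 rose by 1.09 and 0.69 and the NF-kB inhibitor TNFAIP3 by 0.61, while NFKB2, which encodes an NF-kB subunit, had a log2 fold change of -0.68. Of 19 NRF2 targets 5 rose and none fell, also when adjusted over the list alone, among them AKR1C3 at 0.91, SLC7A11 at 0.84, TXNRD1 at 0.49 and the glutathione synthesis gene GCLM at 1.48. G2/M and mitosis genes gave 3 of 22 that rose, BIRC5 at 1.02, KIF23 at 0.38 and CENPE at 0.36, and none that fell (1 and 0 adjusted over the list alone). Camera gave adjusted p = 0.0294 for NF-kB, 0.026 for NRF2 and 0.0408 for G2/M, and the adjusted p with an estimated correlation was 0.474, 0.576 and 0.474. The threshold was missed by the NF-kB list without sgControl replicate 1 (0.0906), by the NRF2 list without sgMETTL13 replicate 2 (0.0519), and by the G2/M list without sgControl replicate 1 (0.0948) or sgMETTL13 replicate 1 (0.106). Without either replicate 2, the NF-kB and NRF2 lists held 2 risen members each, and the G2/M list held 1 without sgControl replicate 2 or sgMETTL13 replicate 1 and 0 without sgMETTL13 replicate 2. CXCL8, TNFAIP3, TXNRD1, GCLM, BIRC5, KIF23 and CENPE lost their calls without at least 1 library.

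Serum had been given 2 h before lysis, and immediate early genes changed in both directions. Of 21 measured in footprints 6 rose and 4 fell (the same adjusted over the list alone). The matricellular genes CCN1 and CCN2, which are also YAP/TEAD targets, rose by 1.23 and 0.98 and the nuclear receptor gene NR4A1 by 0.93, whereas IER2 had a log2 fold change of -1.04. Of 18 YAP/TEAD targets the 2 that rose were CCN1 and CCN2, and 1, AJUBA, fell (log2 fold change -0.85; the same counts adjusted over the list alone). MYC footprints read 666.1 and 698.2 CPM in sgControl and 761.9 and 767.2 CPM in sgMETTL13 (log2 fold change 0.16, SE 0.117), not past the threshold (edgeR adjusted p = 0.332). Among 16 ERK pathway output genes none rose and 1 fell, also when adjusted over the list alone: CCND1, which encodes cyclin D1, had a log2 fold change of -0.71 (SE 0.130), and DUSP6 read 0.56 (SE 0.219) without passing. Camera gave adjusted p = 0.137 for immediate early genes, 0.331 for YAP/TEAD targets and 0.876 for ERK output genes. Immediate early genes passed without sgControl replicate 2 (camera adjusted p = 0.0192).

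In amino acid metabolism, integrated stress response (ATF4) targets gave 7 that rose and 1 that fell of 24 (the same adjusted over the list alone). They included the serine synthesis genes PSAT1 at 1.13 and PSPH at 0.81, the asparagine synthetase gene ASNS at 0.49, and the cystine transporter gene SLC7A11 at 0.84. The list did not pass camera (adjusted p = 0.069), but did without sgControl replicate 2 (0.0188), and ASNS lost its call without sgMETTL13 replicate 2. Among 14 p53 targets 1 rose and 3 fell, also when adjusted over the list alone. CDKN1A, the cyclin-dependent kinase inhibitor p21, had a log2 fold change of -1.29 (SE 0.176), BAX -0.74 and the death receptor gene TNFRSF10B 0.50. TP53INP1 fell on few footprints, with counts of 12 and 8 in sgControl against 3 and 2 in sgMETTL13. The p53 list median was 0.02 and its mean -0.21, and camera gave an adjusted p of 0.872. BAX, TNFRSF10B and TP53INP1 lost their calls without at least 1 library.

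No mRNA passed the test between sgMETTL13 and sgControl. edgeR called 0 of 12468 genes, with 100 at an unadjusted p below 0.05, and DESeq2 and limma voom also called 0. Of the 5 genes with the smallest p, none past the threshold, METTL13 came with PADI3 (log2 fold change -1.89, SE 0.481), UBR7 (2.17, SE 0.603), TMEM50B (3.76, SE 1.08) and NDE1, which had 26 and 7 counts in sgControl against 1 and 0 in sgMETTL13. TMEM50B mRNA read 5.49 CPM in sgMETTL13 replicate 1 and 0.274 CPM in replicate 2, against 0.188 and 0.241 CPM in sgControl. MYC mRNA differed by -0.18 (SE 0.363). NF-kB targets and inflammatory cytokines were the only 1 of 29 lists past camera in mRNA, with a median log2 fold change of 0.38 over 19 members, none of which passed over all genes or adjusted over the list alone (camera adjusted p = 0.0201; adjusted p = 0.898 with an estimated correlation). That list missed the threshold without sgControl replicate 1 (0.2) or sgMETTL13 replicate 2 (0.478).

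The sgMETTL13 RNA replicates differed from each other more than any other pair. The SD of the log2 difference between replicates was 0.923 in sgMETTL13 RNA against 0.391 in sgControl RNA, 0.359 in sgControl footprints and 0.302 in sgMETTL13 footprints. Without sgMETTL13 RNA replicate 1, 27 genes passed in mRNA, and without replicate 2, 2509 passed, 2359 of them higher. Without sgControl replicate 2 the mRNAs that passed were NDE1, GGNBP2, SULT1A3 and POMZP3, the last 3 named after their values were seen, and POMZP3 had counts in sgControl replicate 1 alone. In counts simulated gene by gene with the fitted spread, the RNA test recovered 6% of 2-fold and 70% of 4-fold changes. The footprint test recovered 79% and 94%. The simulated counts held no deviations shared across genes of a library, so recovery in the data may differ.

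**Figure D3:**
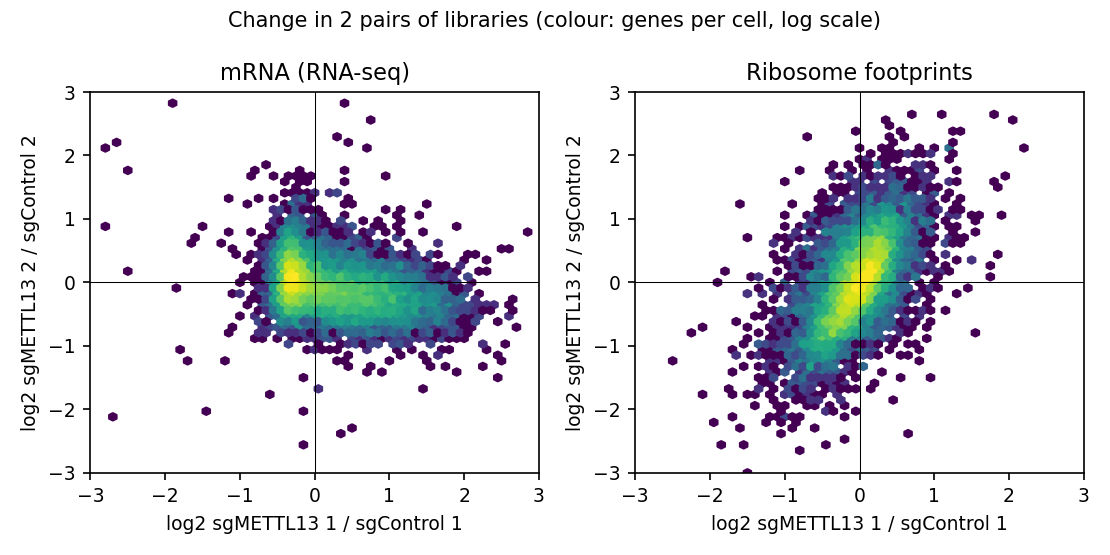
Log2 ratio of sgMETTL13 to sgControl for each gene in the replicate 1 libraries (horizontal) and in the replicate 2 libraries (vertical), for mRNA (left) and footprints (right), over 10446 genes; colour is the number of genes per hexagon on a log scale. The mRNA ratios ran against each other (Pearson r = -0.324 across genes) and the footprint ratios ran together (r = 0.596). The numbers are not stated to pair the libraries, and with them crossed r was -0.666 in mRNA and 0.656 in footprints.

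Translational efficiency, the footprint change relative to the mRNA change, addresses which mRNAs are translated differently with the METTL13 guide. FOXD1 and IER5L, with log2 efficiency changes of -2.51 (SE 0.490) and -2.16 (SE 0.451), and GAGE12G, with 2.38 (SE 0.458), were among the 5 genes with the smallest p. The others were the zinc transporter gene SLC30A5, whose footprint counts were 30 and 39 in sgControl and 5 and 3 in sgMETTL13 (log2 efficiency change -3.96, SE 0.671), and NDE1, whose mRNA was near 0 in sgMETTL13. None of them passed: edgeR's interaction test called 0 of 10446 genes, with 347 at an unadjusted p below 0.05, and limma voom also called 0. DESeq2 called 5, FOXD1, IER5L, GAGE12G, SLC30A5 and HMGA2 (adjusted p = 0.0104, 0.0367, 0.0334, 0.0019 and 0.0334). The GAGE12G efficiency is uncertain, since GAGE copies share reads. Its mRNA read 1.88 and 2.65 CPM in sgControl and 2.70 and 1.60 CPM in sgMETTL13, far below its footprints. Without sgMETTL13 RNA replicate 1, 500 genes passed, 171 with higher efficiency, and without replicate 2, 1384 passed, 126 with higher efficiency.

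EEF1A1 had a log2 efficiency change of 1.05 (SE 0.278) and EEF1A2 of -0.55 (SE 0.404), neither past the threshold. MYC read 0.36 (SE 0.385) and turned to -0.07 without sgControl RNA replicate 2. Of 27 lists 4 passed camera for efficiency, all upward: ribosomal proteins (median 0.38 over 71, adjusted p = 3.3e-11), NRF2 targets (0.21 over 19, 0.0165), initiation factors (0.08 over 35, 0.0165) and replication-dependent histones. Camera compares a list with the other genes, and the median efficiency change over all genes tested was -0.11, so upward is relative to that. The histone value is void, since poly(A) RNA-seq does not measure mRNAs without a poly(A) tail. No member of these lists passed alone or adjusted over the list alone, and with an estimated correlation the adjusted p was 0.565 for ribosomal proteins, NRF2 targets and initiation factors. For ribosomal proteins the estimated correlation was 0.325, against the preset 0.01, so their pass at the preset correlation does not decide. Without sgMETTL13 RNA replicate 1 no list passed. Without sgControl RNA replicate 1 ribosomal proteins alone passed, with a median of 0.10, initiation factors also missed without sgMETTL13 RNA replicate 2, and NRF2 targets also missed without sgMETTL13 RNA replicate 2 or either replicate 2 of footprints.

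Footprint and mRNA fold changes were weakly related across the 10446 genes tested in both assays, with Pearson r = 0.285 and Spearman rho = 0.320. Genes are not independent replicates, so no p is given. The ribosomal protein list had a median of 0.46 in footprints and 0.09 in mRNA, and HMGA2 had -2.00 in footprints and 0.25 in mRNA. The same correlation for the difference between replicates was 0.161 within sgControl and 0.0152 within sgMETTL13. It turned to -0.201 without sgMETTL13 RNA replicate 1.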

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

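Chosen only after the data were seen were the crossed pairing, the removal of a trend on the sgMETTL13 RNA replicate difference, the thinning to the smallest total, the set without copied genes, and the list tests with a library left out. Footprint fold changes correlated with the reported ones under every setting (Pearson r from 0.926 to 1 across genes), but the number of calls depended on the setting. The 2245 footprint calls became 1479 with DESeq2, 333 with a log2 fold change of at least 1, 701 to 3018 with a library left out, and 0 in the fit of all 8 libraries, where RNA libraries widen the spread. Other planned size factors, filters and limma voom gave 2074 to 2481, and the 2181 of limma voom shared 2153 with the reported calls. With no filter 48.2% of the calls were higher, against 42.7%. METTL13 footprints stayed at -1.41 in the 8-library fit without passing. Near-identical copies were genes whose symbols start alike and whose footprint counts lay within 10% of each other in every library. Genes that share reads but differ more in counts were kept, so the histone result in the set without copied genes is not cleared of shared reads. The 8 footprint lists fell to 0 with an estimated correlation or fry, to 2 (histones and NRF2 targets) without genes that have pseudogenes or near-identical copies, which leaves no ribosomal protein to test, and ranged from 5 to 12 with a library left out.

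RNA and efficiency results depended on single RNA libraries. RNA calls were 1 (NDE1) with upper-quartile factors and 0 to 2509 with a library left out, and METTL13 mRNA ranged from -1.68 to -1.13, passing at -1.68. The 1 RNA list became 0 with an estimated correlation or fry and ranged from 0 to 6. EEF1A2 mRNA, near 0 in the main fit, read -0.055 with upper-quartile factors, which lowered RNA fold changes by a similar amount across genes, so that sign carries no information on the gene. With a library left out it ranged from -0.24 to 0.29, and MYC mRNA from -0.48 to 0.24. Efficiency calls were 5 with DESeq2 and 0 to 1384 with a library left out, and the 4 lists became 0 with an estimated correlation or fry and ranged from 0 to 5. METTL13 efficiency turned to -0.0047 with the filter of 50 counts and ranged from -0.29 to 0.30, MYC from -0.074 to 0.67, and the histone list mean, void for want of a valid mRNA value, from -0.63 to 0.66. The correlation of RNA and footprint changes was 0.326 in genes with at least 50 counts and ranged from -0.201 to 0.349. Beyond fewer libraries or genes, the cause was not tested.

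The replicate numbers are not stated to pair the libraries, and same-numbered libraries did not deviate together throughout. The replicate differences of the arms correlated at 0.419 in RNA, -0.173 in footprints and 0.0939 in efficiency. A replicate block left RNA and efficiency at 0 calls and footprints at 1729, and G2/M genes then missed the list threshold (adjusted p = 0.0628). Crossing the footprint pairing gave 3220 calls. The planned codon test was not run.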

Other observations

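Chosen only after the results were seen were the tests of the trend in base composition or gene span, the order of the footprint replicates, and the efficiency calls shared between left-out fits. Members of further gene lists changed in footprints in both directions. So did genes at large, 958 higher and 1287 lower of 10714 tested, so such counts alone do not set a list apart. Of 29 interferon-stimulated genes 10 rose and 3 fell (12 and 4 adjusted over the list alone). B2M rose by 0.77 and IFIT1 by 0.84, while IFITM1 had a log2 fold change of -0.55. The list did not pass camera (adjusted p = 0.069), but did without sgControl replicate 2 (0.0192) or sgMETTL13 replicate 2 (0.0392). Of 23 cholesterol synthesis genes 5 rose and 5 fell (6 and 7 alone), with STARD4 at 0.98 and MSMO1 at 0.67 against MVD at -1.03. Among 18 heat shock and chaperonin genes 5 rose and 2 fell (7 and 2 alone): HSPH1 and HSPA8 rose by 0.42 and 0.38, while DNAJB1 and HSPB1 had -0.998 and -0.615. Of 20 unfolded protein response genes 5 rose and 3 fell (5 and 5 alone), with SEL1L at 0.45, SEC61B at 0.56, HYOU1 at -0.42 and CRELD2 at -0.64. Mitochondrial ribosomal proteins gave 6 that rose and 2 that fell of 34 (7 and 2 alone), MRPS10 at 1.00, MRPS31 at 0.66 and MRPL3 at 0.52 against MRPL4 at -0.88. Camera gave these 4 lists adjusted p of 0.876, 0.217, 0.876 and 0.411.

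Of 23 genes of G1/S and DNA replication 1 rose, PCNA at 0.59, and 2 fell, the DNA methylation factor UHRF1 at -0.69 and the helicase gene MCM2 at -0.37. Of 24 glycolysis and hypoxia genes 1 rose, ANKRD37 at 0.83, and 2 fell, TPI1 at -0.68 and CA9 at -0.74. Among 31 genes of extracellular matrix, integrins and proteases 3 rose, MMP1 at 0.67, ITGA2 at 0.39 and ITGB1 at 0.37, and 2 fell, COL7A1 at -0.53 among them. In the epithelial list ESRP1 rose by 0.50 and ESRP2, its paralog in splicing control, had -0.63, the 2 of 15 that passed, and of 8 mesenchymal markers none passed, SNAI2 reading 0.77 (SE 0.284) and VIM -0.34 (SE 0.144). Of 16 basal-like subtype genes AREG and FGFBP1 rose, by 0.64 and 0.43. Adjusted over the list alone these counts were the same, except that 1 matrix gene fell. Camera adjusted p was 0.876 for the G1/S, glycolysis, epithelial and basal-like lists, 0.906 for matrix and 0.788 for mesenchymal genes. Too few classical subtype genes had footprints for a test, and ANXA10 read 0.17 (SE 0.161) and AGR2 0.72 (SE 0.409). Of other cell types' markers, COL1A1 read -0.15, LCP1 -0.12 and NEFL -0.67 (edgeR adjusted p = 0.00147). Of the genes named here, the calls of B2M, STARD4, DNAJB1, MVD, UHRF1, TPI1, ANKRD37, MRPL4 and AREG held with any 1 library left out, and each of the others that passed lost its call without at least 1.

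RNA replicate 1 of sgMETTL13 stood apart, although its METTL13 level of 25.2 CPM lay with its arm. After thinning to the smallest total, its replicate difference still had 2.34 times the SD of the control pair, against 2.36 before. Unequal counting noise therefore does not account for that difference. Thinning keeps each gene's share of a library, so it cannot tell whether composition differed along with depth. Of other cell types, only fibroblasts, leukocytes and an embryonic kidney line were examined. They are argued against as the whole cause, since their marker sums were 0.706, 1.01 and 0.855 times the highest other RNA library. Few genes carried these sums: COL1A1 most of the fibroblast sum, and NEFL, CDH2 and ZIC2 most of the kidney sum. Each was present in every RNA library, so a small share of such cells could be hidden. LCP1, which T3M4 itself expresses, made up most of the leukocyte sum and could hide a small share, but PTPRC read 0.041 CPM without TMM factors. On the same scale the fibroblast gene COL3A1 read 0.041 CPM, while LUM went the other way at 4.72 CPM against 1.56 or less in the other RNA libraries. PTPRC, COL3A1 and LUM were named after their values were seen. A trend in base composition or gene span may account for part of it, since genes on AT-rich chromosomes (4, 5, 13 and 18) exceeded those on GC-rich chromosomes (16, 17, 19 and 22) by 1.28 on the log2 scale between the sgMETTL13 replicates, against 0.208 between the controls. Against the controls this gap was 0.86 in replicate 1 and -0.287 in replicate 2, so replicate 2 also departed, in the other direction. No biological explanation was tested, and whether the library or the culture differed stays open.

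The footprint log2 fold change of ribosomal proteins had a median of 0.46 and was above 0 in 61 of 72. Removing the trend on the sgMETTL13 RNA replicate difference left the median at 0.51, so the part of a trend that this difference captures does not account for it. The replicate difference also holds noise and base composition was not measured, so a trend in base composition is not excluded here. Sharing of footprints with pseudogenes could not be told apart from a change of the genes themselves: 241 other genes with at least 5 pseudogenes had a median of 0.15 against -0.01 for genes without any, and among ribosomal proteins the change had a Spearman rho of 0.223 with pseudogene number, which did not pass (two-sided permutation p = 0.0599). Ribosomal protein footprints were also far below their mRNA in sgControl, by 3.34 on the log2 scale in the median, against 0.15 for genes without pseudogenes. An effect of the METTL13 guide on translation of these mRNAs stays open, since the list passed camera for efficiency (adjusted p = 3.3e-11) but not with an estimated correlation (adjusted p = 0.565).

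The number of footprint calls was weighed as the last pattern. After thinning all footprint libraries to the smallest total 2056 genes passed, 1932 of them among the reported calls. Counting noise from unequal depth therefore does not account for the number. Thinning keeps the composition of each library, so it cannot exclude a difference in composition that goes with depth. Both sgControl footprint libraries were shallower than both sgMETTL13 footprint libraries. The trend of the odd RNA library may contribute, since footprint changes correlated with its replicate difference across genes (Spearman rho 0.405). Median footprint changes were also 0.262 higher on AT-rich than on GC-rich chromosomes. That gap was 0.139 between the control footprint replicates and -0.0128 between the sgMETTL13 footprint replicates. Once the trend on the RNA replicate difference was removed, 1542 genes passed, against 2229 over the same 10446 genes. That difference also holds noise, and base composition was not measured, so the calls that stayed cannot exclude such a trend as the whole cause. Of the 1542, 1193 were among the reported 2245 calls, so many of those calls were lost. An effect of the guide stays open, as does any difference in handling between the arms, for which the labels give no batch.

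Control footprint replicate 2 lay farther from the sgMETTL13 libraries than control replicate 1 for 2049 of the 2245 calls, 91.3%, and sgMETTL13 replicate 2 lay farther from the controls than replicate 1 for 75.2%. In efficiency, 38 genes passed in the same direction without either sgMETTL13 RNA replicate, 15 higher and 23 lower, while 51 passed in opposite directions. Lists drawn independently would share 2.06 and 39.1 genes, and both fits use the other RNA and footprint libraries, so the overlap is not independent evidence. The 38 included EEF1A1 (0.95 and 1.08), EIF3F (1.09 and 1.51), RPL31 (1.51 and 2.10), HMGA2 (-1.76 and -2.62), FOXD1 (-2.71 and -2.35) and UBE2M (-2.09 and -1.46), of which EIF3F, RPL31, HMGA2 and UBE2M were singled out after their values were seen.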
